A study of Mus musculus with 11 samples.

How the data were processed

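ATAC-seq was measured in 11 libraries of sorted mouse splenic B cells, with groups taken from the titles and genotypes in the labels. Follicular B cells were sorted as B220+ CD93+ CD21+ CD23+, and as tdTomato+ where they came from Cd23-Cre Brwd1fl/fl mice, per the labels' protocols. CD93 is mainly a marker of immature B cells, and the label was taken as given. For GC B cells the sort took cells positive for tdTomato, B220, GL7 and CD95 and divided them by CXCR4 and CD83, per the labels' protocols. The DZp libraries carry GZ in their titles. BWA, Picard, MACS2, bedtools and featureCounts are named, without versions or settings, per the submitters' processing notes, as is the build mm9. The regions of chromosome 1 reach position 197135482, beyond the end of that chromosome in the next mouse build.

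The deposited counts are whole numbers per region and library, with no normalisation by the authors that the values show. They came in 2 tables with separate region sets, 85959 regions for the 5 FolB libraries and 91563 for the 6 GC libraries. Of the regions 52.8% in the FolB table and 67.6% in the GC table overlap a peak of the table's own libraries, 16779 and 22159 overlap no peak of the 11 lists, and 40206 have identical coordinates in both tables. Each library also has a deposited peak list with a score per peak that the authors gave without a unit and that is never below 5. All sample columns matched a label, with 0 left over. Depth was 11551426 to 15945021 counts per FolB library and 18972145 to 29472733 per GC library.

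Regions were filtered with filterByExpr, scaled by TMM (trimmed mean of M-values) and tested with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) with limma 3.58.1 in R 4.3.3. The FolB table was fitted alone, with 3 against 2 libraries. The GC table was fitted once with its 3 groups, and 3 contrasts were taken from that fit. P-values were adjusted by the Benjamini-Hochberg method over the tested regions of each comparison, 85739 for FolB and 91365 for GC, and regions were called at 0.05. Fold changes come from the fitted model at its default settings. CPM values of single regions are counts scaled to TMM library sizes with a prior count of 2 added. At low counts their ratio is therefore smaller than the fold change. They are given as mean and SD over libraries. CPM values of the chromosome 9 stretch are without the prior count. Groups, tests, alternatives and the rule for named regions were fixed before the data were examined. That rule took, in each direction, the 4 regions with the largest change among those past the threshold whose group values did not overlap and whose mean abundance was at least the median. Coordinates are given from 1.

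A second fit used offsets per library from a loess curve (span 0.3) of log counts with a pseudocount of 0.5 on mean abundance, which removes any trend of the fold change with abundance. Regions called in the same direction by both fits are given beside the TMM calls. Chromosome shares of called regions were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over chromosomes and directions within a comparison. Values per library were compared by two-sided exact permutation tests, in which the p of the smaller tail is doubled. Peak lists were compared at an overlap of at least 1 bp, and at 50% of both peaks as an alternative. Stretches of changed neighbours were found as runs of 20 consecutive regions with at least 14 called in the same direction by both fits. Overlapping or adjoining runs were merged and uncalled regions at the ends trimmed, so a stretch can hold fewer or more than 20 regions. The chromosome 8 block was the run with most calls on its chromosome, extended over adjoining regions called higher with TMM and trimmed likewise. These rules were set after the calls were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and bedtools 2.31.1 were used for the rest.

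The fits were tested on simulated data with the real means and library sizes and 200 changed regions, 50 at each of 4 fold sizes. The spread was that fitted to regions of like abundance, with none particular to a region. No trend of the change with abundance was put in. The false calls below therefore do not cover data with such a trend or with many changed regions. For FolB the TMM fit over 85739 regions recovered 2% of the changes of 1.5-fold, 50% of those of 2-fold, 88% of those of 3-fold and 98% of those of 4-fold, with 5 false calls among 124. For LZ versus DZd the TMM fit over 91365 regions recovered 44%, 84%, 100% and 100% at the same sizes, with 5 false calls among 169. At this depth and spread, FolB changes of 1.5-fold were mostly not detectable when few regions changed.

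The alternatives tried were other scaling (DESeq2 size factors, total counts, offsets that follow abundance), other filters on low counts, the Wald test of DESeq2 1.42.0, limma-voom, replicate number as a block, each library left out in turn, regions on X and Y left out, an adjusted p of 0.01, regions with a peak in at least 2 own lists, and GC fits with only the groups compared. A higher score threshold of 15.4 for all peak lists was also tried. Leaving out chromosome 10, leaving out chromosome M and combinations with the offsets were added after the data had been seen. Replicate numbers showed no pairing, since the correlation of residuals between libraries of the same number in different groups ran from -0.02 to 0.04 over all regions and from -0.10 to 0.08 over those above median abundance.

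Tests of gene lists, promoter classes and sequence motifs were planned for an annotation and a genome on mm9. The gene table at hand is on GRCm38, whose coordinates differ, so these tests were not run and no region was given a gene name. For the same reason the counts over Brwd1 were not examined, and the genotype of each library rests on its label.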

Results

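Chromatin accessibility was measured by ATAC-seq, in which a transposase tags open DNA, in 11 libraries of B cells sorted from mouse spleen. The follicular B cells (FolB) are named as in the labels, which give a CD93+ sort although CD93 is mainly a marker of immature B cells. In 3 libraries they came from Cd23-Cre Brwd1fl/fl mice, in which Brwd1, encoding a bromodomain protein that binds chromatin, is deleted (FolB Brwd1KO). The other FolB libraries, 2 in number, came from wildtype mice (FolB WT). A further 6 libraries held germinal centre (GC) B cells of Aicda-Cre Brwd1fl/fl mice immunised with sheep red blood cells, boosted on day 5 and taken on day 14. Each of the 3 GC groups had 2 libraries: LZ cells (CXCR4- CD83+, the light zone phenotype), DZp cells (CXCR4+ CD83+) and DZd cells (CXCR4+ CD83-). In a germinal centre the light zone is where B cells are selected, and CXCR4 is the receptor that holds cells in the dark zone, where they divide and mutate their antigen receptors. No GC library from wildtype mice was analysed here, so the GC comparisons are between cell populations that all lack Brwd1 and give no effect of the deletion. The labels do not say whether replicates are separate animals, so each p-value measures spread between these samples, largely as shared across regions. FolB Brwd1KO cells were also sorted for tdTomato, so sort and genotype differ together.

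The FolB libraries held 11551426 to 15945021 counts over 85959 regions, and the GC libraries 18972145 to 29472733 counts over 91563 regions, on the mouse build mm9. The FolB Brwd1KO libraries held 13852408, 11551426 and 15945021 counts and the FolB WT libraries 12579005 and 14586874. The GC totals were 29177577 and 29472733 for LZ, 19678339 and 18972145 for DZp, and 24310106 and 25007397 for DZd. The variation between replicates, as edgeR's common biological coefficient of variation, was 0.147 in FolB and 0.050 in GC libraries. The weight of the spread shared across regions, as median prior degrees of freedom, was 31.5 in the FolB fit and infinite in the GC fit. For most GC regions the p-value thus does not reflect the spread between that region's own libraries, and very small GC p-values should be read with this limit. No gene annotation on mm9 was used, so regions are named by position and Brwd1 itself was not located in the counts. Single regions named in a comparison, and the gains and losses called its largest, are among those of at least median abundance whose libraries did not overlap between the groups.

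The peak lists of FolB cells without Brwd1 were longer than those of wildtype FolB cells. The own peak lists of the FolB Brwd1KO libraries held 37127 ± 2379 peaks (SD, n = 3) and those of the FolB WT libraries 30488 ± 2853 (SD, n = 2). Every FolB Brwd1KO list was longer than either FolB WT list. The two-sided exact permutation p was 0.2, the smallest that 3 against 2 libraries allow with the tail doubled. On average 90.7% of the peaks of a FolB WT list overlapped a peak of a FolB Brwd1KO list, and 73.8% the other way round. Among GC groups LZ had most peaks, at 53370 and 56126, then DZd, at 46427 and 47718, then DZp, at 43579 and 39112. The peak numbers of these 3 groups did not overlap and followed the order of their total counts in LZ, DZd and DZp. In each pair of GC groups the two-sided exact permutation p was 0.333, the smallest that 2 against 2 libraries allow. Of the peaks of a DZp list 95.4% on average overlapped a peak of an LZ list, and 70.6% of those of an LZ list overlapped a peak of a DZp list.

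**Figure D1:**
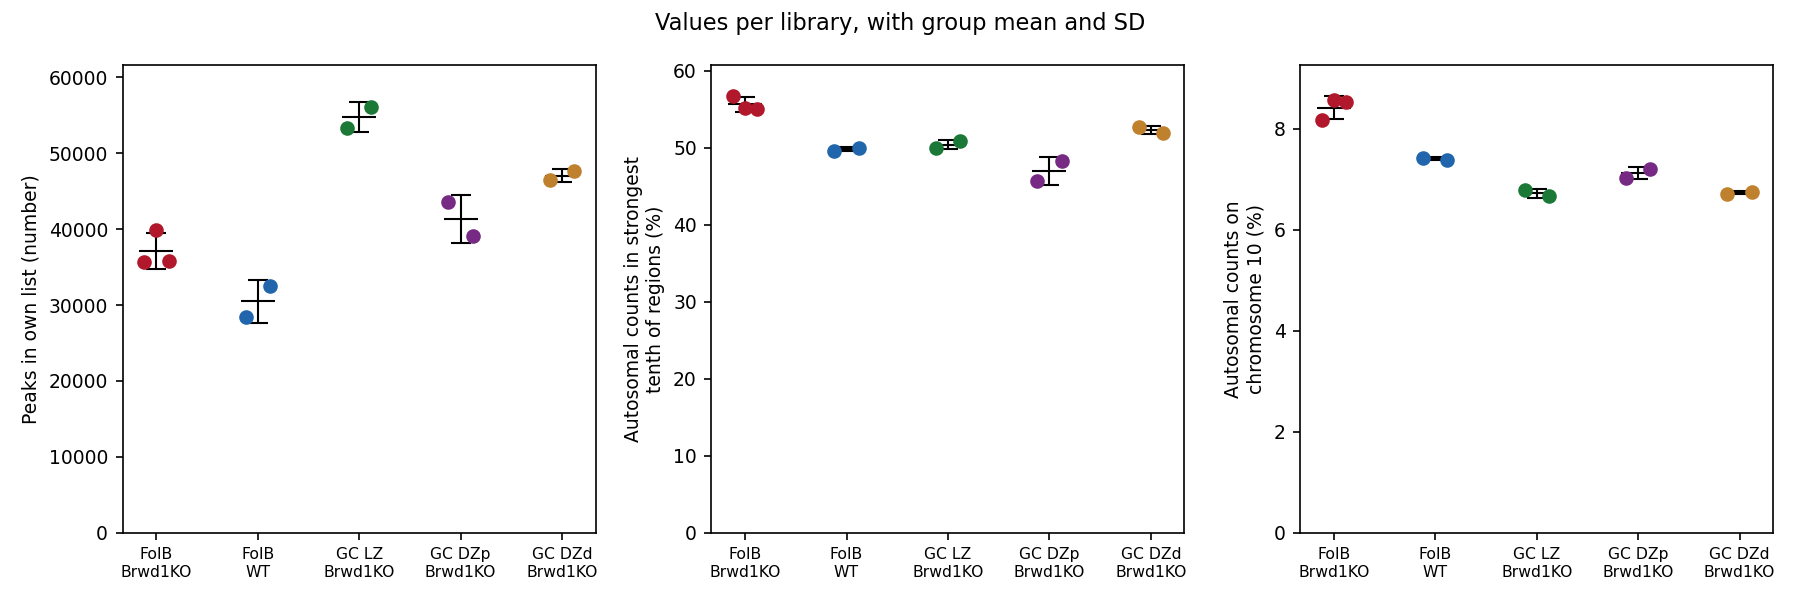
Number of peaks, percent of autosomal counts in the strongest 10% of regions and percent of autosomal counts on chromosome 10, with each library as a point and the group mean and SD as bars (n = 3 for FolB Brwd1KO, n = 2 for each other group). The FolB Brwd1KO libraries lie above the FolB WT libraries in all 3 measures.

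The first comparison asked how follicular B cells that lack Brwd1 differ from wildtype follicular B cells in accessible regions. Of 85739 regions tested, 13733 were higher and 8195 lower in FolB Brwd1KO, of which 2139 and 2163 changed by at least 2-fold. The largest gain in a region with a peak was at chromosome 9 115043616–115044968, with a normalised read count of 30.5 ± 4.23 CPM (SD, n = 3) in FolB Brwd1KO and 3.15 ± 0.510 (SD, n = 2) in FolB WT, a 10.1-fold difference. The largest loss was at chromosome 10 59908431–59908785, with 1.77 ± 0.593 CPM (SD, n = 3) against 27.7 ± 2.77 (SD, n = 2), 16.4-fold lower. Gains and losses were not spread evenly over the genome. Chromosome 10 carried a larger share of gains than other chromosomes, and 16 of 17 regions in 1 stretch of chromosome 9 were lower.

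Among regions higher in FolB Brwd1KO, a region of chromosome 10 at 50946271–50946672 gained 9.55-fold and a region of chromosome 3 at 4029857–4030268 gained 8.99-fold. A region of chromosome Y at 2776963–2777168 gained 23.4-fold, with 114, 101 and 139 counts in FolB Brwd1KO and 8 and 4 in FolB WT, but it overlapped no peak in any of the 5 FolB lists. Over all of chromosome Y, FolB Brwd1KO replicate 3 held 85874 counts and the other FolB libraries 1406 to 3220. Among regions lower in FolB Brwd1KO, chromosome 9 105973950–105974670 lost 11.8-fold, chromosome 9 104666108–104666712 lost 9.40-fold and chromosome 5 18962896–18963247 lost 7.98-fold. These 8 regions passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p from 8.45e-15 at chromosome 10 59908431–59908785 to 4.52e-06 at chromosome 5 18962896–18963247. By the rule for named regions, every library of 1 genotype lay above every library of the other in each of them.

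On chromosome 10, 2669 of 7062 tested regions were higher in FolB Brwd1KO, or 37.8% against 14.1% on the other chromosomes (odds ratio 3.71, Fisher's exact test with Benjamini-Hochberg adjustment over chromosomes and directions). The chromosome held 8.42% ± 0.220 of autosomal counts in FolB Brwd1KO (SD, n = 3) and 7.40% ± 0.0308 in FolB WT (SD, n = 2), with a two-sided exact permutation p of 0.2. It also held 11.2% ± 0.219 of FolB Brwd1KO peaks (SD, n = 3) and 9.59% ± 0.0765 of FolB WT peaks (SD, n = 2). Of 120 windows of 1 Mb along the chromosome, 86.7% had a median change above 0 with offsets that follow abundance. Chromosome 11 went the other way, with 7.91% of its regions higher against 16.6% elsewhere and 14.3% lower against 9.20% elsewhere. Smaller leanings were seen on further chromosomes in both directions. Chromosome 17 had 10.0% of its regions higher against 16.3% elsewhere and 12.8% lower against 9.41%. Chromosome 3 had 19.4% higher against 15.8% and 7.12% lower against 9.68%. The cause of these leanings was not tested. Neighbouring regions are not independent replicates, so these tests describe where called regions lie.

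**Figure D2:**
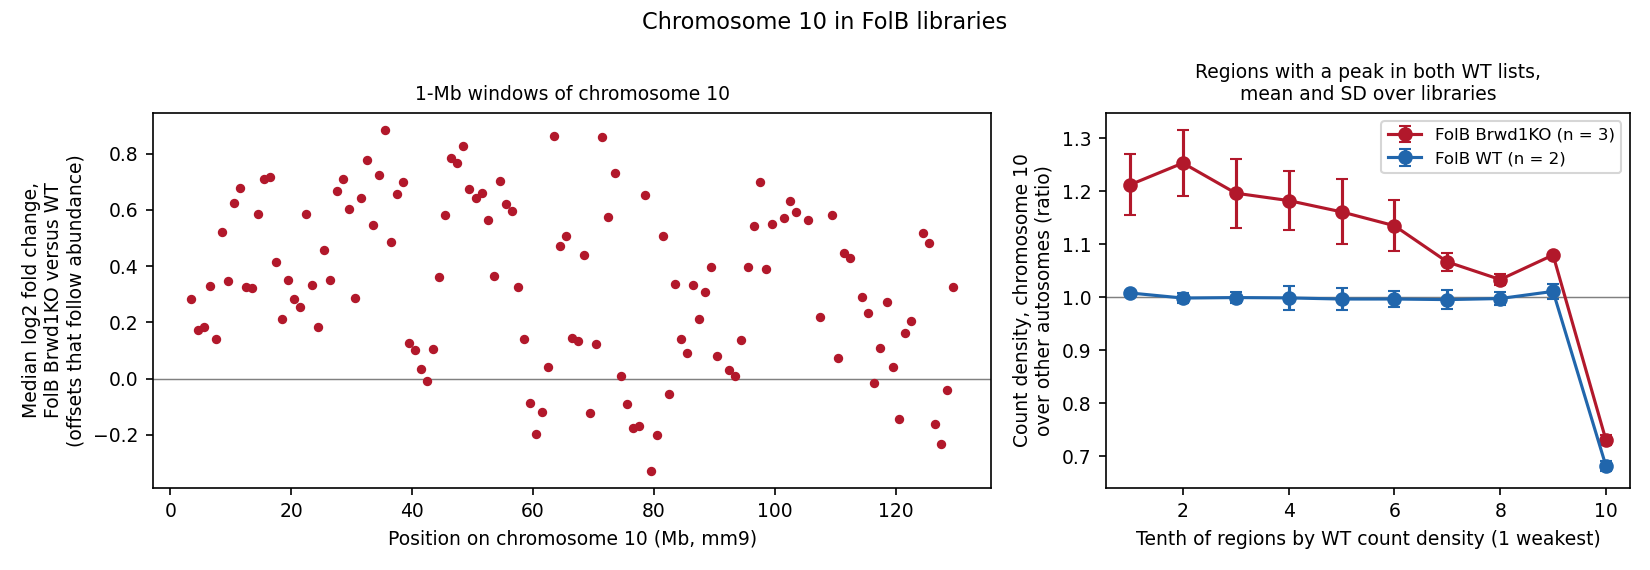
Left, median log2 fold change of FolB Brwd1KO over FolB WT in 1 Mb windows along chromosome 10 (mm9), with offsets that follow abundance and each window as a point. Right, count density of chromosome 10 over that of other autosomes among regions with a peak in both FolB WT lists, in 10 groups by density in FolB WT, as mean and SD over libraries (n = 3 and n = 2), which is 1.21 in group 1 and 1.08 in group 9 in FolB Brwd1KO.

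A pair of stretches, chosen after the calls were seen, held neighbouring regions that changed together. At chromosome 8 3627993–3719186, 19 of 20 regions were higher in FolB Brwd1KO, with a median log2 fold change of 0.93. The 10 regions nearest to this block had a median of 0.01. At chromosome 9 104217808–104875514, 16 of 17 regions were lower in FolB Brwd1KO, with a median log2 fold change of -1.90. The stretch held 29.0, 26.7 and 29.4 CPM in the 3 FolB Brwd1KO libraries and 108 and 117 in the FolB WT libraries. Each FolB Brwd1KO list had 1 peak there, against 11 and 10 in the FolB WT lists.

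The change also depended on how accessible a region was. The median log2 fold change ran from -0.45 in the weakest 10% of regions to 0.38 in the strongest 10%. The strongest 10% of regions took 55.6% ± 0.965 of autosomal counts in FolB Brwd1KO (SD, n = 3) and 49.8% ± 0.276 in FolB WT (SD, n = 2), with a two-sided exact permutation p of 0.2. After offsets that removed this trend, 6711 of the higher and 3412 of the lower regions were called in the same direction, and at 2-fold 2115 and 998. With these offsets chromosome 10 had 29.8% of its regions higher against 6.98% elsewhere. Calls were made with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05. With total counts in place of TMM scaling, which moved the median log2 fold change of all regions to -0.33, 17.1% of called regions were higher in place of 62.6%. The 21928 calls became 12301 without FolB Brwd1KO replicate 1, 6946 without FolB WT replicate 1 and 9588 without FolB WT replicate 2.

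**Figure D3:**
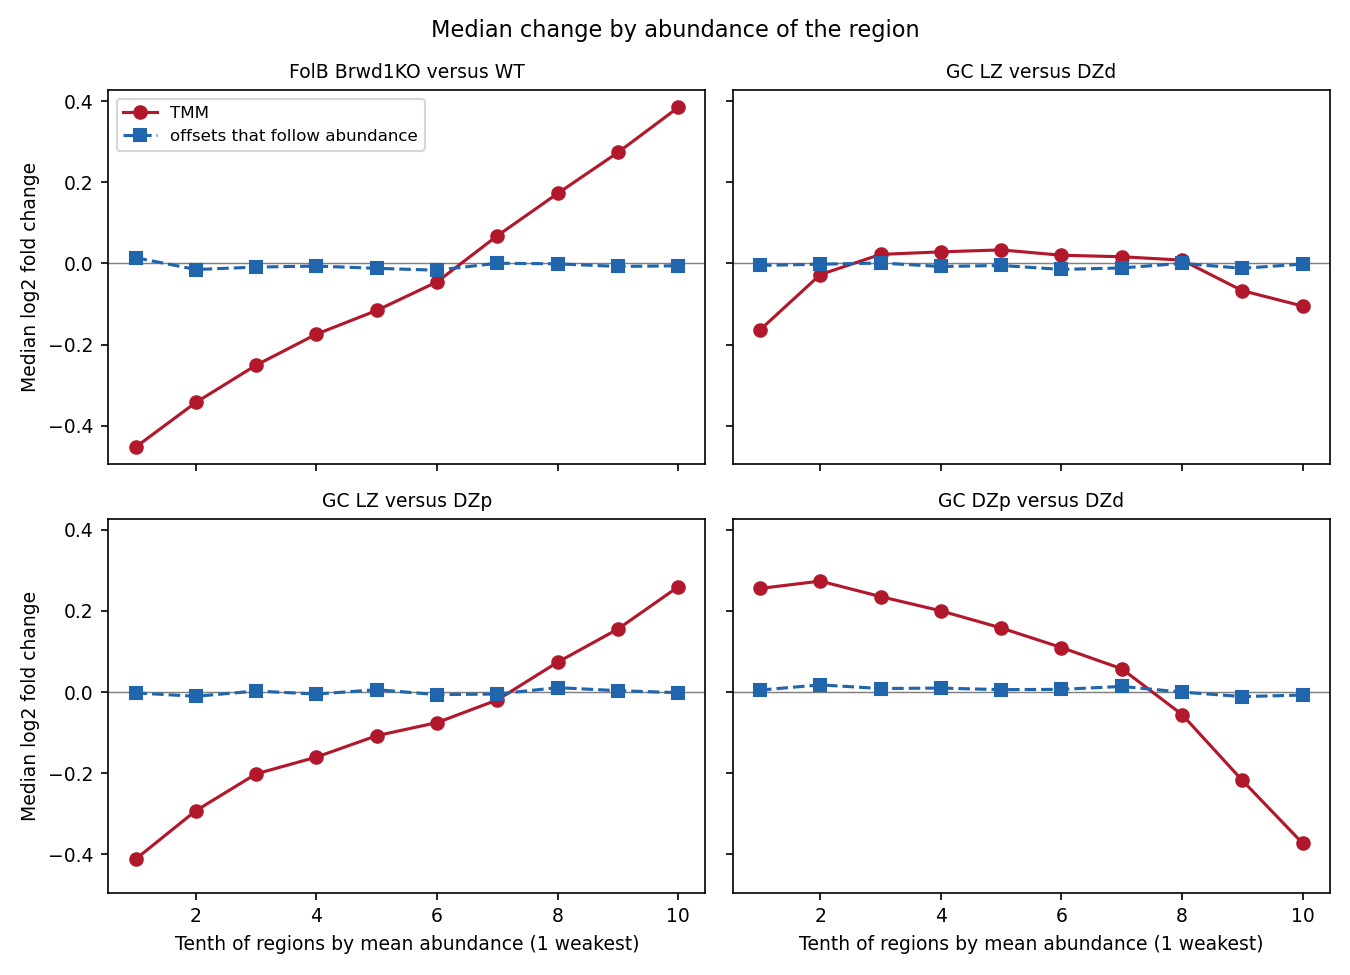
Median log2 fold change in 10 groups of regions by mean abundance for each of the 4 comparisons, with TMM scaling (circles) and with offsets that follow abundance (squares). With TMM the FolB medians rise from -0.45 to 0.38, the LZ versus DZp medians rise from -0.41 to 0.26 and the DZp versus DZd medians fall from 0.26 to -0.37.

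The second comparison set LZ against DZd cells, the populations that differ in both CXCR4 and CD83. Of 91365 regions tested, 8037 were higher and 7621 lower in LZ, of which 505 and 187 changed by at least 2-fold, and 505 and 127 of these were also called in the same direction with offsets that follow abundance. The region with the largest gain in LZ was chromosome 19 29330831–29331358, at 9.22 ± 1.41 CPM in LZ and 2.24 ± 0.0671 in DZd (SD, n = 2 each), 4.23-fold higher. The region with the largest loss was chromosome 1 194620916–194621657, at 2.91 ± 0.307 CPM in LZ and 10.4 ± 0.138 in DZd (SD, n = 2 each), 3.64-fold lower. A stretch of chromosome 4 at 32344590–32675910, chosen after the calls were seen, had 33 of 43 regions higher in LZ, with a median log2 fold change of 0.85.

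Other regions higher in LZ than in DZd were chromosome 18 56893405–56894086 (3.64-fold), chromosome 3 109550432–109551207 (3.44-fold) and chromosome 2 6519278–6520232 (3.20-fold). Regions lower in LZ included chromosome 2 165336453–165337452 (2.85-fold), chromosome X 10946034–10947285 (2.44-fold) and chromosome 18 65581001–65581825 (2.42-fold). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 1.01e-36 for the chromosome 19 region and 1.10e-36 for the chromosome 1 region. By the rule for named regions, both libraries of 1 group lay above both of the other in all 8 regions. Of the called regions 7195 higher and 6375 lower in LZ were called in the same direction after offsets that follow abundance. Chromosome 11 had 12.5% of its regions lower in LZ against 8.02% elsewhere (odds ratio 1.64, Fisher's exact test with Benjamini-Hochberg adjustment). With total counts in place of TMM, 65.3% of called regions were higher in LZ in place of 51.3%. The 15658 calls became 8493 without LZ replicate 2, 8483 without DZd replicate 1 and 8411 without DZd replicate 2, where the lone library of an arm was taken to vary like the other groups.

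**Figure D4:**
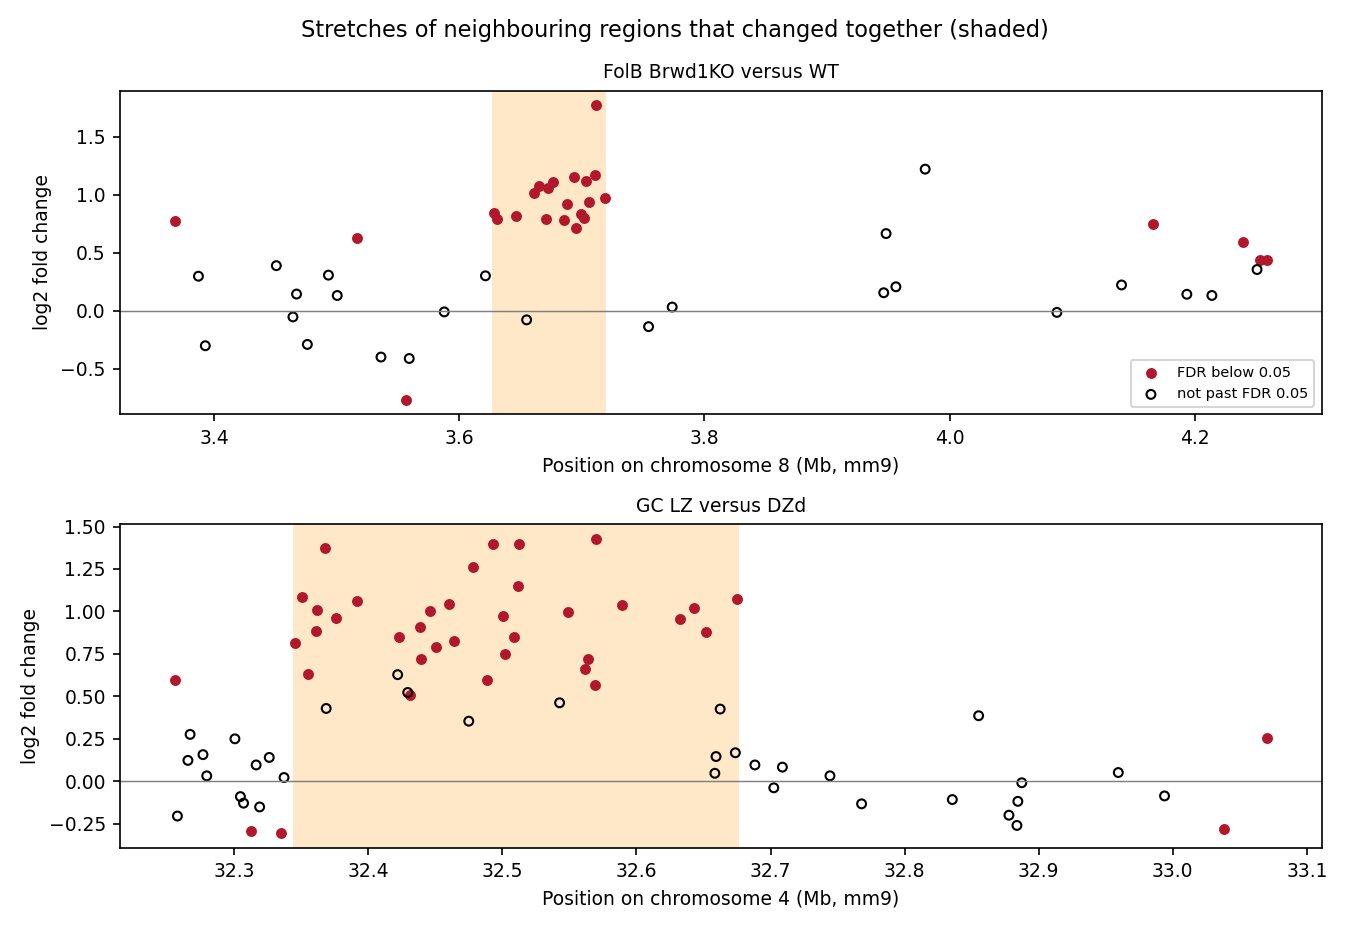
Log2 fold change of each region along chromosome 8 for FolB Brwd1KO over FolB WT (top) and along chromosome 4 for GC LZ over DZd (bottom), against position on mm9, with regions at an adjusted p under 0.05 filled and others open. The shaded stretches hold 19 called regions of 20 on chromosome 8 and 33 of 43 on chromosome 4.

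The third comparison set LZ against DZp cells, which share CD83 and differ in CXCR4. In LZ 14043 regions were higher and 12024 lower, of which 113 and 978 changed by at least 2-fold, and 113 and 475 of these were also called in the same direction with offsets that follow abundance. At chromosome 4 88035761–88037037 LZ held 19.0 ± 2.01 CPM and DZp 6.77 ± 0.321 (SD, n = 2 each), 2.83-fold higher in LZ, with an adjusted p of 2.10e-38 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At chromosome 3 14983578–14983867 LZ held 6.07 ± 0.440 CPM and DZp 15.5 ± 3.85 (SD, n = 2 each), 2.58-fold lower in LZ. The regions on chromosome 18 and chromosome 3 that were higher in LZ than in DZd, at 56893405–56894086 and 109550432–109551207, were also higher in LZ than in DZp, by 2.83-fold and 2.74-fold.

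The largest gain in LZ over DZp was 2.97-fold at chromosome 11 42499721–42500129. Other regions lower in LZ were chromosome 17 54370260–54370553 (2.42-fold), chromosome 5 107901968–107902347 (2.35-fold) and chromosome 17 70497691–70498008 (2.32-fold), and these passed the same test. On chromosome Y 78 of 131 regions were lower in LZ, or 59.5%, and 39 with offsets that follow abundance. Chromosome Y held 0.0955% and 0.0675% of counts in the LZ libraries and 0.121% and 0.133% in the DZp libraries. The labels do not give the sex of the mice, so these calls cannot be read as a difference in accessibility alone. Chromosome 10 had 21.9% of its regions lower in LZ against 12.1% elsewhere, and 10.6% against 8.51% with those offsets (Fisher's exact test, Benjamini-Hochberg adjustment). Strong regions were higher and weak regions lower in LZ, with medians from -0.41 to 0.26 between the weakest and the strongest 10%, and 7358 higher and 5562 lower regions were called in the same direction after offsets that follow abundance. With total counts in place of TMM, which moved the median log2 fold change of all regions to -0.15, 32.6% of called regions were higher in LZ in place of 53.9%. The 26067 calls became 17045 with those offsets, 11133 without LZ replicate 2 and 16348 without DZp replicate 1.

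The fourth comparison set DZp against DZd cells, which share CXCR4 and differ in CD83. In DZp 7615 regions were higher and 14277 lower, of which 401 and 52 changed by at least 2-fold, and 235 and 51 of these were also called in the same direction with offsets that follow abundance. The largest gain was at chromosome X 137170490–137171144, at 14.8 ± 3.07 CPM in DZp and 2.67 ± 0.788 in DZd (SD, n = 2 each), 5.66-fold higher, with an adjusted p of 9.87e-66 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At chromosome 1 72279971–72281184 DZp held 29.1 ± 3.70 CPM and DZd 71.9 ± 4.17 (SD, n = 2 each), 2.48-fold lower in DZp. The chromosome 3 region at 14983578–14983867 that was lower in LZ than in DZp was also 5.14-fold higher in DZp than in DZd, and the chromosome 11 region at 42499721–42500129 that was higher in LZ than in DZp was 3.13-fold lower in DZp than in DZd.

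Other regions higher in DZp were chromosome 1 123561315–123561591 (4.76-fold) and chromosome 7 138420336–138420644 (4.36-fold), and other regions lower in DZp were chromosome 15 87798250–87798675 (2.24-fold) and chromosome 2 110133623–110134011 (2.12-fold). These passed the same test. The chromosome 11 region was not assigned an adjusted p by DESeq2's Wald test. With offsets that follow abundance, chromosome X had 8.41% of its regions lower in DZp against 3.42% elsewhere (odds ratio 2.59, Fisher's exact test with Benjamini-Hochberg adjustment). With TMM this share was 14.7% against 15.7% elsewhere and did not pass. The calls depended on the scaling. With offsets that follow abundance 1915 of the higher and 2882 of the lower regions were called in the same direction, 3198 calls changed sign, and the split became 49.3% higher in place of 34.8%. With total counts the split was 71.2% higher and the median log2 fold change of all regions moved to 0.23. The 21892 calls became 6460 with offsets that follow abundance, 10124 without DZd replicate 1 and 11600 without DZp replicate 1.

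**Figure D5:**
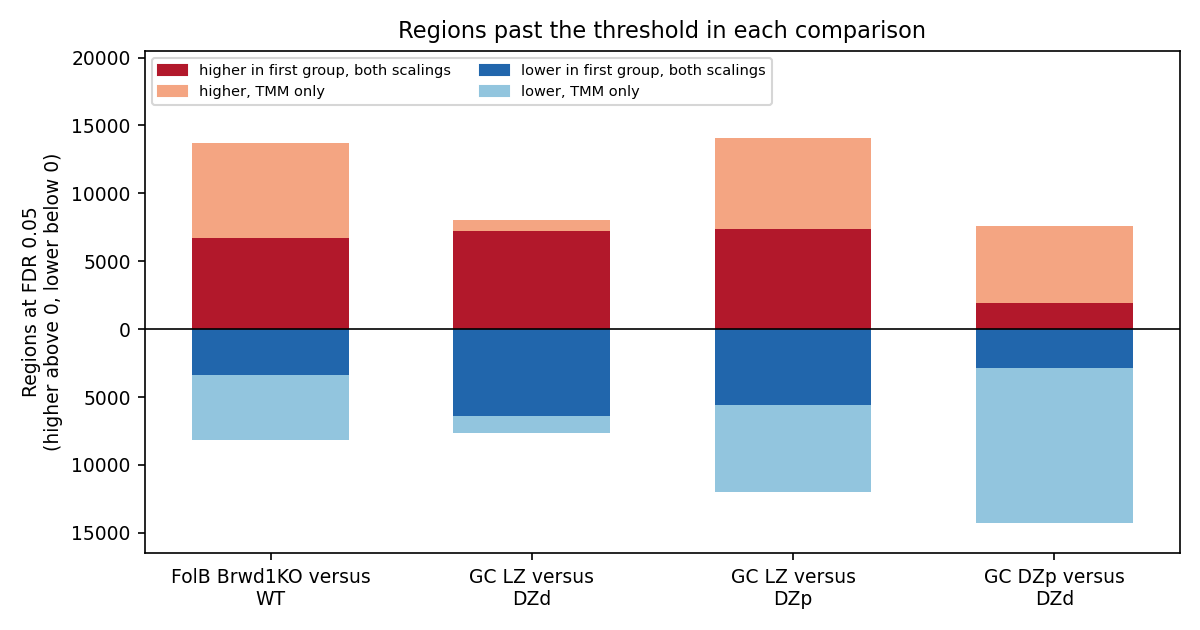
Number of regions past an adjusted p of 0.05 in each of the 4 comparisons, higher in the first-named group above 0 and lower below it. Dark bars count regions called in the same direction with TMM and with offsets that follow abundance, such as 6711 higher and 3412 lower in FolB Brwd1KO, and light bars count those called with TMM alone.

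The position of DZp was measured at regions called between LZ and DZd, a choice that favours a value between them, and no share by chance was computed. Where 0 is the LZ value and 1 the DZd value, the median position of DZp was 0.608 over the 8037 regions higher in LZ and 0.360 over the 7621 regions higher in DZd. With offsets that follow abundance it was 0.697 and 0.612, and DZp lay between the other populations at 71.2% and 70.7% of the regions. With TMM it lay between them at 70.8% and 49.8%, so the share for regions higher in DZd moved with the scaling. All 3 GC comparisons share libraries and are not independent of each other.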

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

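The tests that left out chromosome 10 or chromosome M, or joined offsets with another change, were chosen after the results were seen, and the others before the data were examined. The number of called regions stayed within 1.5 times its value in 13 of 20 alternatives for FolB Brwd1KO versus WT, 16 of 21 for LZ versus DZd, and 15 of 21 each for LZ versus DZp and DZp versus DZd. For FolB it was 11685 with DESeq2's Wald test, 12727 with offsets that follow abundance and 11608 at an adjusted p of 0.01, the last by construction. With only regions in at least 2 peak lists, 36536 regions were tested with scaling computed anew, and 9466 were called. Of these, 6226 were also called in the same direction in the main fit. The Wald test and an adjusted p of 0.01 gave 4041 and 9216 for LZ versus DZd, 10783 and 15966 for LZ versus DZp, and 11715 and 13991 for DZp versus DZd. Offsets that follow abundance, alone and with a replicate block, gave 17045 and 17075 for LZ versus DZp and 6460 and 6558 for DZp versus DZd. For FolB they gave 12727 and 22720. Total counts reversed the majority direction, to 17.1% higher for FolB, 32.6% for LZ versus DZp and 71.2% for DZp versus DZd. DESeq2's Wald test kept it, at 85.2%, 85.6% and 4.69% higher. It gave an adjusted p to only 77391, 59480 and 45310 regions, against 85739 for FolB and 91365 for GC in the main fits. These shares cover fewer regions and are not a like comparison. Leaving out 1 library gave 6946 to 29339 calls for FolB, 8411 to 16818 for LZ versus DZd, 11133 to 24472 for LZ versus DZp and 10124 to 21741 for DZp versus DZd, and the cause was not tested. The lowest values came without FolB WT replicate 1, DZd replicate 2, LZ replicate 2 and DZd replicate 1, and an arm with a lone library was assumed to vary like the other groups. FolB Brwd1KO replicate 3, with its high chromosome Y counts, was left out of both fits, giving 29339 calls with TMM and 20120 with offsets that follow abundance. A replicate block gave 30905 calls for FolB, 14405 for LZ versus DZd, 24631 for LZ versus DZp and 20592 for DZp versus DZd, although the numbers showed no pairing. Replicate 3 exists only in FolB Brwd1KO, so for FolB the block fits that library exactly and takes it out of the contrast. The FolB value is thus no separate check from the fit without that library. The ratio of FolB Brwd1KO to FolB WT peaks was 1.22, with 1.34 at a higher score and 1.14 to 1.3 with 1 library left out. Of 658 recomputed fold changes of the 32 named regions, 657 kept their direction and their side of the threshold and 0 reversed. A region named in more than 1 comparison counts once in each. These regions were picked for large changes past the threshold in the same counts, which favours this outcome. The exception was chromosome 11 42499721–42500129 in DZp versus DZd, which DESeq2's Wald test gave a log2 fold change of -1.67 but no adjusted p. For other moved values the cause was not tested. Alternatives planned for gene lists, promoters and motifs were not run.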

Other observations

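Apart from the count of calls with offsets that follow abundance, which was planned before the data were examined, the tests and stretches in this part were chosen after the results were seen. On chromosome 10, 26 stretches held 771 regions called higher of 1075. Counts at neighbouring regions of other chromosomes were also higher together in FolB Brwd1KO. DNA copies at these stretches were not measured, so higher counts there cannot be read as accessibility alone. At chromosome 6 68070753–69808563, 73 of 101 regions were higher, with a median log2 fold change of 0.86. Over the regions shared with the GC table this stretch held 1.93% ± 0.238 of the counts of its chromosome in FolB Brwd1KO (SD, n = 3), 1.31% ± 0.00547 in FolB WT (SD, n = 2) and 0.751% ± 0.0120 in GC LZ cells (SD, n = 2). Gains also ran together at chromosome 2 175100126–176817490 (27 of 33 regions), chromosome 3 106276901–106693397 (19 of 27), chromosome 5 62965550–64158352 (21 of 30), chromosome 12 35407695–35724645 (16 of 23) and chromosome 14 16180524–17006706 (19 of 27). Losses ran together at the start of chromosome 3, at 3000187–3137911 (17 of 25), and of chromosome 17, at 3006442–3078007 (14 of 19). Stretches overlapping these were also lower in LZ than in DZp (21 of 26 and 20 of 20). They were higher in DZp than in DZd (16 of 19 and 19 of 19). A stretch overlapping that of chromosome 2 was higher in LZ than in DZp (31 of 43) and lower in DZp than in DZd (25 of 34). Changes at these places are therefore not particular to the genotype comparison. In GC cells a stretch of chromosome 16 at 24506328–24828970 had 22 of 33 regions higher in LZ than in DZd, with a median log2 fold change of 0.65. Stretches at chromosome 5 14401483–15209597 (66 of 83) and chromosome 8 19511823–22087662 (61 of 83) were lower in LZ than in DZp.

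Regions called in both FolB and GC comparisons were compared by sign. Over 38243 autosomal regions with identical coordinates in both tables, 3475 were called both in FolB Brwd1KO versus WT and in LZ versus DZp, and 73.4% of them had the same sign, against 49.1% if the calls were independent. With offsets that follow abundance 70.9% of 1353 had the same sign, against 50.8%. For LZ versus DZd the share was 62.5% of 1508 regions and 68.2% of 897 with the offsets, and for DZp versus DZd it was 19.6% of 2360 and 32.9% of 484. Across all these regions the fold changes were weakly related, with Spearman correlations to LZ versus DZp, LZ versus DZd and DZp versus DZd of 0.167, -0.0113 and -0.189, and 0.159, 0.0565 and -0.123 with the offsets. Regions are not independent replicates, and no test of these shares was run. The share of FolB regions called higher was 19.9% where at least 2 GC lists had a peak and 9.82% where none had, but 7.71% and 11.6% with the offsets, so its direction turned with the scaling. FolB Brwd1KO replicate 3 had 120 peaks on chromosome Y, and the other FolB libraries 6 to 8.

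The gain over most of chromosome 10 in FolB Brwd1KO was weighed against 3 technical explanations. Extra copies alone would raise all its regions by 1 factor. They are argued against by regions with a peak in both FolB WT lists. There the log2 excess of the less over the more accessible was 0.20 (SD 0.05, n = 3) on chromosome 10 and -0.07 to 0.06 on 18 other autosomes. Medians of 1 Mb windows had an SD of 0.30, and 0.29 with offsets that follow abundance. These lay narrowly above the highest of other autosomes, 0.28 and 0.27. A constant factor would leave this SD unchanged, so it does not bear on extra copies. The ratio of chromosome 10 to other autosomes fell by 0.640 (SD 0.173, n = 3) from the weakest of 10 density groups to group 9, a drop that regions picked from FolB Brwd1KO peaks may add to, and in regions with a peak in both FolB WT lists by 0.133 (SD 0.0592, n = 3), which alone does not pass a margin of 0.1 plus 2 SD. A general difference in signal over background is argued against by the 29.8% of chromosome 10 regions called higher with offsets that follow abundance, against 6.98% elsewhere, and a choice of regions from FolB Brwd1KO peaks by the less accessible regions that had a peak in both FolB WT lists, where the ratio was still 1.22 ± 0.0619 (SD, n = 3). The large number of regions and peaks on chromosome 10 was not particular to FolB Brwd1KO. It had the most tested regions of any chromosome, 7062 in the FolB fit and 10271 in the GC fit. It held 9.59% ± 0.0765 of FolB WT peaks (SD, n = 2). Of its 10390 GC regions, 4589 overlapped no peak of the 11 lists, against 22159 of all 91563. What this adds to the gain was not tested. A candidate explanation that stays open is a gain of low-level accessibility along the chromosome in FolB cells without Brwd1, with or without extra copies. It was not tested directly, and neither was a difference in strain background between the mice.

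The block of chromosome 8 at 3627993–3719186 had a median change of 1.90-fold in FolB Brwd1KO, and 1.69-fold with offsets that follow abundance. The trend with abundance is argued against as its cause, since the median log2 fold change was 0.75 after its removal. Extra DNA copies of the block, as a transgene that carries this stretch would bring, may account for it: its more abundant regions rose less than its less abundant ones, by -0.22 on the log2 scale (bootstrap SE 0.10, over 2 SE from 0, though within the first margin used, an SD of 0.29 over single regions), but 27.0% of 3781 runs of 20 neighbouring regions elsewhere, a comparison added after that SE was seen, differed by as much, so copies are neither supported nor excluded. In the 6 GC libraries, also without Brwd1 but made with another Cre, the block held 0.600% ± 0.0253 (SD, n = 6) of the chromosome 8 counts at shared regions, near FolB WT at 0.605% ± 0.0126 (SD, n = 2) and below FolB Brwd1KO at 1.03% ± 0.0808 (SD, n = 3). Without wildtype GC libraries, an effect of the deletion on this block and one of the Cre line cannot be told apart.

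Strong regions were higher and weak regions lower in FolB Brwd1KO across the genome. Depth is argued against as the cause, since library totals of the genotypes overlapped while the lowest FolB Brwd1KO library exceeded the highest FolB WT library by 5.00 percentage points of counts in the strongest 10% of regions. Chromosome M held 8.54% ± 0.464 of counts in FolB Brwd1KO (SD, n = 3) and 6.70% ± 0.729 in FolB WT (SD, n = 2). A region of chromosome 1 at 24618398–24623000, counted among the strongest autosomal regions, held 2.84% to 4.42% of all counts across the FolB libraries. What it adds to the difference in the strongest 10% was not tested. With offsets that remove the trend with abundance 12727 regions were called, of which 10123 were among the 21928 TMM calls in the same direction, but as all FolB Brwd1KO libraries lay on 1 side, signal over background of the preparations and an effect of the deletion cannot be told apart.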
